A study of Mus musculus with 9 samples.

How the data were processed

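Total RNA from brain tissue of 8-month-old mice, 5 wild type and 4 knockout for CAIX, was purified on RNeasy columns, turned into biotin-labelled cRNA with an Illumina TotalPrep kit and hybridised to single-colour Illumina bead arrays, per the labels' protocols. The design text counts 5 and 4 mice, so each array was treated as 1 animal. Scanner software, slides and hybridisation dates were not given in the sources used here.

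The authors deposited a table of signals with, per the file headers, no normalization, and a table of processed values. The signals are intensity values on a linear scale, the mean over the beads of a probe, as deposited by the authors, and their medians differed between arrays from 133.2 to 209.8. Beside each signal the authors deposited a fraction that the file headers call a detection p-value. It rose with the signal on every array (lowest rank correlation 0.992), so 1 minus the fraction was used as the detection p. The processed values are log2 values, per the range of the deposited numbers. They were recovered to within 0.012 by quantile normalization of the linear signals followed by log2, without background correction or centring, and every column had a median of 7.52. That is a calculation from the values, since the authors' steps are not given in the sources used here.

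Group labels were in conflict. Titles and genotype characteristics name different genotypes for 6 of the 9 samples, although both give 5 wild type and 4 knockout. Titles were taken as the main grouping and the characteristic as another grouping, before the data were examined, as were the tests, the gene lists, the rule for named genes and the alternatives. A further conflict appeared in the values: 4 arrays lie under different samples in the signal table and in the processed table. The headers of the signal table were followed. This leaves 4 readings of the groups, and counts are given for each. Arrays are named by the title that the signal table's header leads to.

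Of 46120 rows in the signal table, 4 bacterial control rows absent from the processed table were left out. Signals of the other 46116 probes were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp background from the detection p, quantile normalization, log2, offset 16). Probes with a detection p under 0.05 on at least 4 of the 9 arrays were kept, 16375 in all. Knockout and wild type were compared per probe with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Every adjusted p for a probe comes from limma. A probe with a detection p of 0.05 or more on every array of a group has only a bound there. The bound is the brighter group's mean minus the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal.

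The files pair no probe with a gene. Names were taken from a RefSeq gene table of assembly GRCm38.p6, from which no coordinate is printed. Identifiers of one format carry a number that was read as an NCBI gene number. Of 10024 such numbers 81.1% were in the table, against 42.5% to 45.9% after adding or subtracting 1 to 3, so the reading is an inference that fits most but not provably all of them. Clone names and RefSeq accessions inside identifiers named a few more. In all 10824 probes were named, 9832 by number, 983 by clone and 9 by accession. Of the kept probes 4930 (30.1%), for 4396 genes, had a name, and the rest are unnamed here. No probe matched Car9.

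A set of 38 gene lists was fixed beforehand. Each gene entered with the probe of highest mean signal, and the 30 lists with at least 3 measured genes were tested with camera of limma (inter-gene correlation 0.01), adjusted over those 30 lists. An estimated correlation was the alternative. Text-named items are every probe past the threshold by title and then those of smallest p with a symbol, to 24 probes, then 12 by genotype characteristic, and up to 4 members of smallest p from each list, of which 2 are given for most lists. Some members that this rule selects are left out of the text, while the list tests and counts include them. Where another kept probe of a named gene had the opposite sign, it is given.

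The per-probe test was checked on simulated data with the spread of the 16375 kept probes and 5 against 4 arrays. Of 200 probes changed by 0.5 on the log2 scale, 76.5% were recovered, and 96.5% of those changed by 1. With no probe changed, 0 were called. The noise was drawn independently for each probe and array. Correlation between probes and differences that many probes share between arrays were thus left out. These values therefore do not give the recovery or the error rate on the real arrays. The number of arrays limits the precision. Alternatives tried were the other readings of the labels, both labels in one fit, other filters, background corrections and normalizations, array weights, a mean-dependent and robust prior, the replicate number as a block, sex as a covariate, and leaving out each array in turn. Added after seeing the data were the processed values matched to arrays by their content, the processed table's array assignment, choroid plexus transcripts as a covariate, and the correlation of list genes estimated within other settings. The block of slides planned beforehand was not run because no slide is named.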

Results

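Gene expression was measured on bead arrays in brain tissue of 8-month-old mice, 5 of them wild type and 4 lacking CAIX. CAIX, carbonic anhydrase IX, is the product of Car9 and a membrane enzyme that converts carbon dioxide and water to bicarbonate and protons at the cell surface. The design implies 1 comparison, knockout against wild type, in a series whose title speaks of neurological defects of the knockout. Between 14895 and 17325 probes per array were above background, and 16375 probes were compared. Arrays correlated with each other at r = 0.975 to 0.994 over these probes.

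Car9 itself could not be read, since no probe was matched to it, and its level was not analysed here. The identity of the groups rests on labels that conflict. Titles and genotype characteristics differed for 6 of 9 samples, and the deposited tables placed 4 arrays under different samples. Only wild type 1, wild type 2 and knockout 1 had the same group in all 4 readings.

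The probe NeoR-S carries the name of the neomycin resistance gene, a selection marker often used in gene targeting. It was above background on all 4 arrays titled knockout and on 0 of the 5 titled wild type, with means of 10.21 ± 0.34 (SD, n = 4) and 6.81 ± 0.017 (SD, n = 5). The signal was at least 9.59-fold higher in the knockout (limma, adjusted p = 1.46e-05). None of 23 other probes for reporter, resistance, recombinase or viral sequences passed the filter, and their highest value on any array was 7.02. The labels do not say whether the targeted allele carries this marker. With the genotype characteristic as the group, NeoR-S was above background on 3 of 5 wild-type and 1 of 4 knockout arrays. With titles read through the processed table it was above background on 2 of 5 and 2 of 4, and with the characteristic read through that table on 1 of 5 and 3 of 4.

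**Figure D1:**
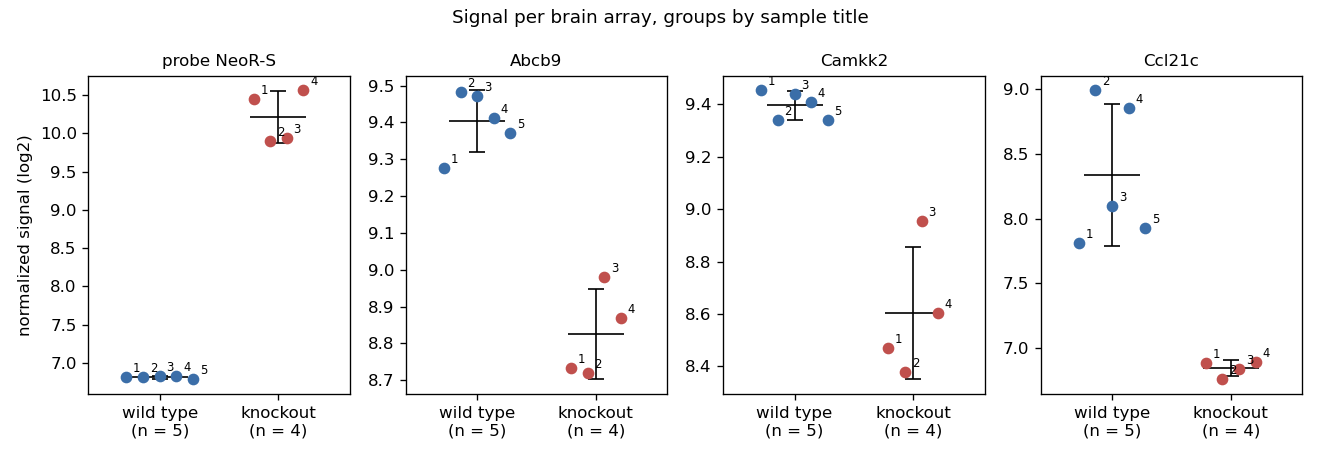
Normalized log2 signal (vertical axis) of probe NeoR-S and of probes for Abcb9, Camkk2 and Ccl21c on each array, grouped by title (horizontal axis). Points are arrays with their replicate number, and bars show mean and SD (n = 5 wild type, n = 4 knockout). NeoR-S lay near 6.81 on the wild-type arrays and near 10.21 on the knockout arrays.

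By title, 4 probes passed the threshold, 3 higher and 1 lower in the knockout. Beside NeoR-S they were Abcb9 and a pair of unnamed probes. Abcb9, a lysosomal peptide transporter, was lower, at 8.83 ± 0.12 (SD, n = 4) against 9.40 ± 0.084 (SD, n = 5), a log2 difference of -0.58 (SE 0.067, adjusted p = 0.0431). Its call was lost without wild type 1, 2, 3, 4 or 5 (adjusted p = 0.0577, 0.203, 0.137, 0.0661 and 0.151), without knockout 2 or 4 (0.208 and 0.0527), and with no filter (0.0707), no background correction (0.0519), cyclic loess (0.0647), median scaling (0.302), the replicate block (0.287) or sex as a covariate (0.0858). Of the alternatives run, its call was kept in 4: without knockout 1 (0.0384), without knockout 3 (0.0258), with array weights (0.0296) and with the processed values matched to arrays by content (0.0496). The unnamed probe scl24403.4_53-S was at least 1.39-fold higher (adjusted p = 0.000757) and scl25514.12.16_2-S at least 1.20-fold higher (adjusted p = 0.0166). Neither was above background on any wild-type array. The call of scl25514.12.16_2-S was lost without wild type 1, 2, 3 or 5 (adjusted p = 0.0577, 0.0988, 0.0896 and 0.0930), with median scaling (0.128), with sex as a covariate (0.0612) and with both labels in one fit (0.0793). Both unnamed probes, scl24403.4_53-S first, lost theirs with the replicate block (0.234 and 0.287) and with the arrays whose labels are the same (0.348 and 0.673). At an unadjusted p under 0.05 there were 1876 probes, 11.5% of those tested. Without knockout 1, 48 probes passed, 30 higher and 18 lower, 16 of them with a name. They included Hspd1, the mitochondrial chaperonin (log2 difference 0.45, adjusted p = 0.0306), Prmt1, an arginine methyltransferase (-0.94, adjusted p = 0.0129), and Tardbp, the RNA-binding protein TDP-43 (0.71, adjusted p = 0.0338), which are named after their values were seen. Without that array all knockout arrays have low Xist and 2 of 5 wild-type arrays high Xist, so sex and group are partly confounded in this fit. The first principal component is the axis of largest variation between arrays over the kept probes. On it knockout 2, 3 and 4 lay at 5.41, 8.73 and 26.13. Wild type 4 lay at 3.90 and the other wild-type arrays at -12.15 to -2.56. Group and this axis are thus partly confounded in this fit as well. Without wild type 1, 2, 3 or 5 in turn, 2 probes passed in each case, and 7 passed without knockout 3.

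The named genes that followed did not pass the threshold, and their values are given without a call. Ccl21c, a chemokine that guides lymphocytes and dendritic cells through the receptor CCR7, was above background on all 5 wild-type and on 0 of 4 knockout arrays, at least 2.62-fold lower in the knockout (adjusted p = 0.124). Camkk2, a calcium- and calmodulin-dependent kinase kinase, had a log2 difference of -0.79 (SE 0.10, adjusted p = 0.0770). Kinase and phosphatase genes in this group were Araf (0.30), Map3k11 (-0.39) and Dusp8 (-0.53). Genes of membrane traffic and lipid binding were Snx30 (0.45), Osbp2 (-0.34), Tex261 (-0.41) and Rabgap1 (0.33). Of these, Snx30 lies within 20 Mb of Car9 in the gene table. Transcription and chromatin factors were Mafg (-0.65), Kctd1 (-0.58), Morf4l2 (0.27) and Brwd1 (0.73). Another probe of Brwd1 differed by -0.055. Pum2, an RNA-binding translational repressor, differed by -0.25, Srxn1, which reduces oxidised peroxiredoxins, by -0.30, and Ndst1, a heparan sulfate enzyme, by -0.45. Jup, a junction protein, differed by -0.57, Ranbp1, a Ran-binding protein, by 0.24, Dab2ip, a Ras GTPase-activating protein, by -0.42, and Mprip, a myosin phosphatase partner, by -0.26. Adjusted p of the 20 named genes past the fourth probe ran from 0.0770 to 0.172.

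Among 30 gene lists tested, 1 passed the threshold. The oligodendrocyte and myelin list was lower in the knockout in 6 of 6 measured genes, with a median log2 difference of -0.35 (camera, adjusted p = 0.0122). With an estimated correlation of its genes this call was lost, with an adjusted p = 0.906. Mobp, a myelin structural protein, differed by -0.63 (SE 0.38), Cnp, an enzyme of myelinating cells, by -0.38 (SE 0.099), Trf, the iron carrier transferrin, by -0.38 (SE 0.17), and Fa2h, which makes hydroxylated myelin lipids, by -0.33 (SE 0.19). None passed over all probes, and 1, Cnp, did so adjusted over the list alone. Cnp was at 8.39 ± 0.21 (SD, n = 5) in the wild type and 8.02 ± 0.065 (SD, n = 4) in the knockout. The call was also lost without knockout 1 (adjusted p = 0.0622), wild type 3 (adjusted p = 0.0719) or knockout 4 (adjusted p = 0.0725). The mean of the list, relative to all arrays, was 0.408, 0.217 and 0.427 on wild type 1, 2 and 3. Wild type 4 (-0.162) lay among the knockout arrays (-0.129, -0.0585, -0.178 and -0.491), and wild type 5 (-0.0349) lay just above them. The glucocorticoid list was highest on wild type 1, 2 and 3 as well, at 0.396, 0.570 and 0.198. Those 3 arrays and knockout 1 stand first in the sample order. Knockout 2, 3 and 4 come after them with wild type 4 and 5, so group and order are partly confounded. The median signal was 209.8 on wild type 1, the first array, and 133.2 on knockout 4, the last. What the order reflects is not given. The Mobp value of knockout 4, 8.42, lay far below those of the other knockout arrays, and without it the difference of Mobp was -0.18. That array stood apart more widely, with the lowest median signal (133.2) and list means of -0.309 for synaptic vesicle, -0.263 for learning and 0.307 for ribosomal protein genes.

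**Figure D2:**
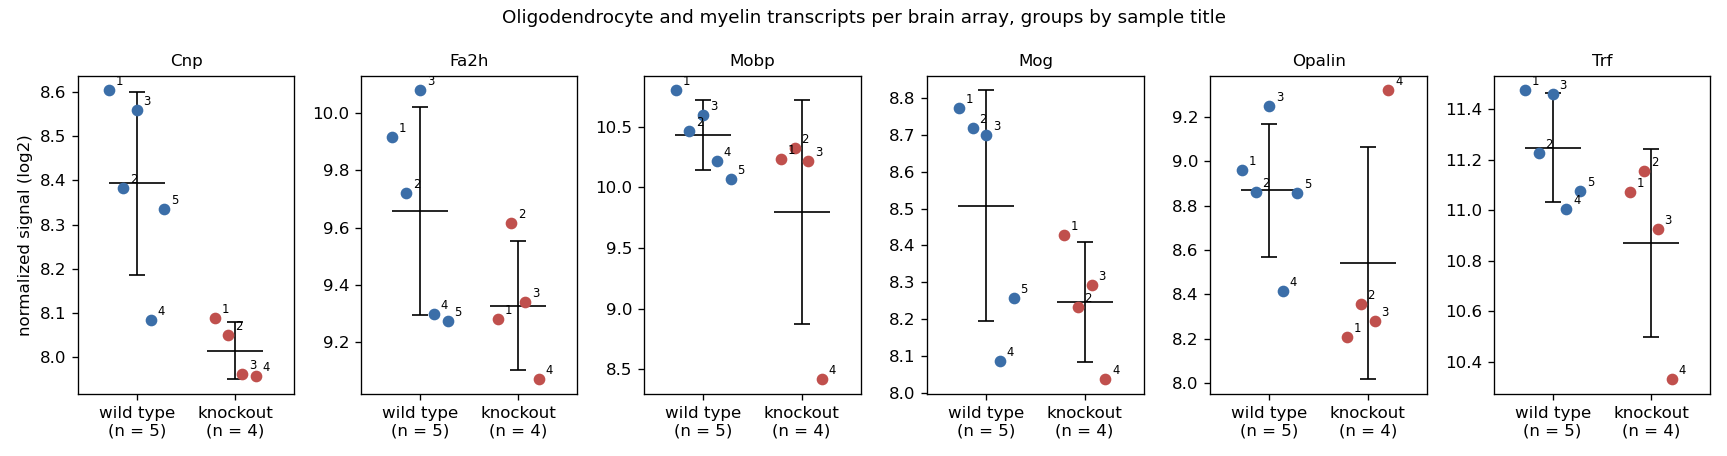
Normalized log2 signal (vertical axis) of the 6 measured oligodendrocyte and myelin transcripts on each array, grouped by title (horizontal axis). Points are arrays with their replicate number, and bars show mean and SD (n = 5 wild type, n = 4 knockout). Cnp averaged 8.39 in the wild type and 8.02 in the knockout, and the Mobp point of knockout 4 lies at 8.42.

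Lists of the other cell types did not pass. Of 65 list members given, myelin genes included, 40 had a value that moved by over 1.5 times when some array was left out, and 4 changed sign (Dcn, Col8a1, C4b and Pecam1), so single values are descriptive. All 5 measured astrocyte genes had lower means in the knockout (adjusted p = 0.481), among them Fgfr3 (-0.28) and Apoe (-0.12). Microglial genes went both ways, 3 higher and 2 lower (adjusted p = 0.975), with Cd53 at 0.12 and Csf1r at -0.22. Of 7 glutamatergic genes 4 were lower (adjusted p = 0.725), with Grin1, an NMDA receptor subunit, at -0.40 and Dlg4, the postsynaptic scaffold PSD-95, at -0.55 (-0.33 without knockout 4). Grin1 passed adjusted over the list alone. Of 4 GABAergic genes 3 were higher (adjusted p = 0.671), with Reln at 0.29. Synaptic vesicle genes were higher in 4 and lower in 6 (adjusted p = 0.759), with Syt1 at 0.17. Of 8 genes of learning, plasticity and neurotrophins 6 were lower (adjusted p = 0.688), with Gap43 at 0.18 and Mapt at -0.23. Of 5 blood genes 4 were higher (adjusted p = 0.671), with S100a9, a neutrophil protein, at 0.67 and Cd74 at 0.069.

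Lists tied to the enzyme and to metabolism did not pass either. Among 10 acid-base and lactate transport genes 5 were higher and 5 lower (adjusted p = 0.975), with Slc4a4, a sodium-bicarbonate cotransporter, at -0.24. Of 8 hypoxia-responsive genes 6 were lower (adjusted p = 0.635), with Egln1, an oxygen-sensing hydroxylase, at -0.32 and Pgk1 at 0.19. Egln1 passed adjusted over the list alone. Glycolysis genes were higher in 8 and lower in 7 (adjusted p = 0.977), with Pgk1 again first and Eno2 at -0.077. Oxidative phosphorylation genes were higher in 12 and lower in 17 (adjusted p = 0.676), with Ndufb3 at 0.14 and Sdhb at -0.18. Of 9 cholesterol synthesis genes 6 were lower (adjusted p = 0.355), and 2 passed adjusted over the list alone, among them Srebf2 (-0.37), the regulator of the pathway. Fdps was at -0.20. Ribosomal protein genes were higher in 18 and lower in 6 (adjusted p = 0.671), with Rpl11 at 0.12 and Rpl3 at 0.073.

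Stress and response lists also stayed above the threshold. Of 7 glucocorticoid-responsive genes 4 were lower (adjusted p = 0.355), with Cdkn1a at -0.87, Sgk1 at -0.85, Arrdc2 at -0.47 and Errfi1 at -0.23. Cdkn1a passed adjusted over the list alone. The 3 immediate early genes were lower (adjusted p = 0.481), with Egr2 at -0.49 and Junb at -0.46. Of 10 heat shock genes 6 were higher (adjusted p = 0.676), with Hspd1 at 0.33 and Hspe1 at 0.29. Of 5 apoptosis genes 3 were lower (adjusted p = 0.759), and 2 passed adjusted over the list alone, Bcl2 (0.22) and Cdkn1a. Interferon genes were higher in 2 and lower in 3 (adjusted p = 0.905), with Irf9 at -0.061 and B2m at 0.15. Gliosis and complement genes were higher in 3 and lower in 2 (adjusted p = 0.671), with Spp1 at 0.39 (0.14 without knockout 2) and C4b at 0.078 (-0.012 without knockout 1). Of 9 lysosome and autophagy genes 6 were higher (adjusted p = 0.671), with Becn1 at 0.15 and Ctsz at 0.11. Of 3 circadian clock genes 2 were higher (adjusted p = 0.759), with Nr1d2 at 0.14 and Npas2 at -0.091.

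Region markers did not separate the groups. All 3 striatal genes had lower means in the knockout (adjusted p = 0.635), with Drd1 at -0.99 (SE 0.65, and -0.44 without knockout 2) and Ido1 at -0.38. Hippocampal genes were higher in 3 and lower in 2 (adjusted p = 0.759), with Fibcd1 at 0.56 (0.13 without knockout 1) and Bok at -0.23, thalamic genes 2 and 2 (adjusted p = 0.894), with Rora at -0.23 and Ntng1 at 0.21, and choroid plexus genes 1 and 3 (adjusted p = 0.975), with Col8a1 at 0.064 (-0.024 without knockout 1) and Clic6 at -0.35. Of 5 olfactory bulb genes 4 were higher (adjusted p = 0.481), and Dcx, a protein of migrating young neurons, was at 0.36 and passed adjusted over the list alone. Genes near Car9 were higher in 6 and lower in 4 (adjusted p = 0.676), with Unc13b, a synaptic vesicle priming factor, at 0.72 and Reck at 0.086. Reference transcripts were higher in 6 and lower in 4 (adjusted p = 0.759), with Actb at -0.14 and Pgk1 as above. Sex-linked genes gave an adjusted p = 0.759. The remaining 8 lists had fewer than 3 measured genes and no test. Car15 (0.037) stood for the carbonic anhydrases, Neu4 (-0.045) for oligodendrocyte precursors, Nkx2-1 (-0.12) for the hypothalamus and Sag (0.079) for pituitary and pineal. Egfl7 (0.083) and Pecam1 (-0.017) stood for endothelium and pericytes, and Dcn (0.50, but -0.045 without knockout 1) and Mgp (0.26) for meninges and fibroblasts. No gene of the ependyma or cerebellum list was measured.

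Grouped by the genotype characteristic, 0 probes passed (limma, smallest adjusted p = 0.952), with 669 at an unadjusted p under 0.05. The 12 named genes had values without a call. Nos1ap, an adaptor of neuronal nitric oxide synthase, differed by 0.54, Rnf167, a ubiquitin ligase of endosomes, by 0.56, Plec, a cytoskeletal linker, by 0.36, Kcnma1, a calcium-activated potassium channel, by 0.33, Afdn by 0.35, Trps1 by 0.35, Cttnbp2 by 0.29 and Qrich1 by 0.22. Lower means were seen for Plekha1 (-0.27), Desi2 (-0.26), Rpap2 (-0.26) and Prpf3 (-0.22). Of the gene lists 0 passed (smallest adjusted p = 0.126). Over all kept probes the log2 differences by title and by characteristic correlated at r = -0.523 across probes, which are not independent replicates, and 35.8% had the same sign. With no effect, the shared arrays alone would give r = -0.35. With titles read through the processed table, limma called 0 probes, with 615 at an unadjusted p under 0.05, and with the characteristic read through it 0 passed, with 391.

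With both labels in one limma fit, the title term had 3 probes past the threshold and the characteristic term 0, with 1656 and 653 at an unadjusted p under 0.05. Of the 3, 2 were among the 4 found by title alone. NeoR-S had an adjusted p = 0.000163 along the title and 1 along the characteristic. Between the arrays whose labels were the same, 1 knockout and 2 wild type with the spread pooled over the label combinations, NeoR-S was the only probe that passed (limma, adjusted p = 0.0278). The lone knockout array was assumed to vary like the others.

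Sex-linked transcripts divided the arrays across the groups. Xist, the RNA that coats the inactive X chromosome, was between 10.46 and 10.89 on wild type 1, wild type 2 and knockout 1, and between 6.83 and 6.93 on the other 6 arrays. The Y-linked Eif2s3y was between 6.79 and 6.87 on those 3 arrays and between 7.44 and 8.08 on the other 6, and Kdm5d between 6.77 and 6.81 against 6.95 and 7.17. The labels give no sex. With sex as a covariate 2 probes passed by title.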

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

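All tests of explanations in this part were chosen after the result was seen, except the count of splits for the gene lists.

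In 200 groups of arrays tested, 18 held an array far from the rest of its group. The groups were limited to the items named in the text, after a wider set had been looked at. Chance alone gives about 1 in 20 for independent items. These items share the same 9 arrays, so 18 cannot be read as an excess over chance. Knockout 4 had a median signal of 133.2 against 182 for the nearest knockout array. On that array Mobp was 8.42 where the nearest was 10.21, Junb 8.15 where the nearest was 7.44, and Opalin, a myelin protein, 9.32 where the nearest was 8.35. On knockout 1, Prlr was 8.24, Col8a1 7.29, Brwd1 7.61, Car15 6.89 and the Y-linked Eif2s3y 6.79. That array is the only knockout array with high Xist. On wild type 5, Osbp2 was 9.48, Egfl7 7.69, Mgp 9.40 and NeoR-S 6.78, the last within the background. On wild type 4, Dcx was 7.49, Srebf2 8.95 and Unc13b 8.75. On wild type 3, Jup was 8.78 and Morf4l2 12.04.

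NeoR-S was bright on the arrays titled knockout. By those titles, read through the signal table, NeoR-S left 0 of 9 arrays out of place, which restates the pattern and is no test of the titles. If NeoR-S marks the targeted allele, that the genotype characteristic holds the true groups would leave 6 arrays out of place, and that the array assignment of the series matrix holds the true groups would leave 4 by title and 2 by genotype characteristic. A candidate explanation is a selection marker left in the targeted allele. It stays open, because the labels do not describe the allele and no Car9 probe was matched.

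The Ccl21 probes were near background on the arrays titled knockout, with Ccl21a at 7.47 ± 0.30 (SD, n = 5) in the wild type and 6.80 ± 0.038 (SD, n = 4) in the knockout, at least 1.44-fold lower. Whether the 2 kept Ccl21 probes read separate copies of the family was not tested. A strain variant in the region around Car9 stays open, since the family lies near Car9 in the gene table. Among 59 other measured genes within 20 Mb of Car9, 14 (23.7%) had an unadjusted p under 0.05. Elsewhere 11.6% of 4337 genes did (Fisher's exact test, two-sided, p = 0.00746), and 0.124% of 4035 overlapping windows elsewhere had as high a share. Of the 14 genes, 10 were higher in the knockout and 4 lower. At an unadjusted p under 0.01, the threshold tried first, the counts were 3 and 177 (Fisher's exact test, p = 0.734). The windows and the demand that both thresholds pass were added after these values were seen, so this test decides nothing. A variant linked to Car9 would be carried by the same animals that lack CAIX. A linked strain variant and an effect of CAIX loss therefore cannot be told apart here. Fisher's test here counts genes as units although all share the same arrays, so its p does not measure variation between animals. Among the 14 genes, Snx30 (0.45) had the smallest p. In the list of genes near Car9 fixed beforehand, 1 of 10 measured genes had an unadjusted p under 0.05 (camera, adjusted p = 0.676).

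Choroid plexus transcripts differed between arrays of the same group. Clic6, an ion channel protein, was between 8.21 and 9.32 on wild type 1, 2, 3 and knockout 1 and between 7.01 and 7.67 on the other 5 arrays. The list mean divided the same way, at 8.14 to 9.04 against 7.76 to 7.94. Not every member did so, and Col8a1 had its lowest value, 6.88, on wild type 1. Wild type 1, 2, 3 and knockout 1 are also the arrays that stand first in the sample order. The 4 measured transcripts had a mean pairwise r of 0.859 over the arrays and an estimated correlation of 0.899, and the striatal and thalamic lists were about as tight, at 0.893 and 0.812, so that other amounts of choroid plexus in the tissue taken stay open and untested. The list mean ranged over 0.915 within the wild type and 1.28 within the knockout and differed by -0.084 between the groups, which restates a pattern defined within groups and is no test of genotype. An array-wide shift of equal size for all signals is argued against. Without normalization between arrays, the choroid plexus mean ranged over 1.2 and the reference transcript mean over 0.334. At least 1.06 of the choroid plexus range was left after subtracting the reference transcripts, whichever of them was left out. With such unequal ranges most of it had to be left, so the subtraction adds little. It replaced a test on normalized signals that had left the question open, and was set after those values were seen. A shift that varies with signal strength was not tested.

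Of 126 possible splits of the 9 arrays into 5 and 4, 100 were run, those by title and by genotype characteristic among them. At least the 4 probes found by title came from 3 of the 100, the title split included. Not every split was run and the test was chosen after the result, so chance stays open. Wild type 1, 2 and 3 with knockout 1, first in the sample order, against the rest gave 9 probes. The highest other split gave 185. That split set knockout 2, 3 and 4 with wild type 4 against the rest, which points to a structure of the samples. It differs from the titles by the exchange of knockout 1 and wild type 4 and has the 3 arrays with high Xist on one side. Its 4 arrays lay at 3.90 to 26.13 on the first principal component, which held 30.3% of the variance over the kept probes. The other 5 arrays lay at -12.15 to -2.56. The split thus divides the arrays along that axis, and what the axis reflects was not tested. By genotype characteristic 0 probes were found, so all 100 splits gave at least as many by construction, which says nothing about chance, and the highest other gave 185. For the gene lists 80 of 100 splits gave at least the 1 list found by title, so chance cannot be excluded for the myelin list. The highest other gave 8 lists. That split set wild type 4, wild type 5, knockout 3 and knockout 4, last in the sample order, against the rest. It too points to a structure of the samples, so the count of splits does not separate chance from that structure.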

How the results depend on the processing

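Array assignment by the processed table, its values matched by content, the choroid plexus covariate, and the correlation estimated within other settings were chosen after seeing the data. Causes were not tested except where stated. The 4 probes found by title became 0 with the genotype characteristic, the authors' series matrix values or the array assignment of the series matrix, 1 with only the arrays whose labels are the same or with the replicate block, 2 with median scaling or sex as a covariate, 7 with a trend and robust prior, 8 with the choroid plexus covariate, 11 without background correction and 13 with matrix values matched by content. With a detection p under 0.01 on all 9 arrays it was 0: that filter removes NeoR-S and both unnamed probes, and Abcb9 then had an adjusted p of 0.0661. Leaving out 1 array gave 2 to 48, the highest without knockout 1. With no filter, cyclic loess, array weights or both labels it was 3 to 6. By genotype characteristic it was 0 in every alternative, leaving out 1 array included. The title term of the fit with both labels gave 0 with detection on all 9 arrays, 8 without background correction and 1 with median scaling, and the contrast of arrays with the same labels gave 0, 2 and 1, and 0 without a filter or with cyclic loess. Same-numbered arrays had correlations of deviations of 0.101, 0.0885, -0.309 and 0.0113, and 1 of 4 knockout arrays correlated best with its own number, so the numbers were not taken as pairs.

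Named probes past the threshold reversed with the genotype characteristic, to log2 differences of -1.08 for NeoR-S, -0.19 for scl24403.4_53-S, -0.18 for scl25514.12.16_2-S and 0.18 for Abcb9. All 24 probes named by title changed sign there, which is largely set by labels that oppose each other on 6 of 9 arrays and is no separate evidence, 3 did so with the series matrix values, 2 with its array assignment, and 0 under the other alternatives. Signs of genes without a call were not counted as reversals.

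The number of lists past the threshold was 0 with the genotype characteristic, array weights or an estimated correlation, 2 with both labels, 3 with the array assignment of the series matrix, and 5 with the series matrix values or the arrays whose labels are the same. Leaving out 1 array gave 0 to 2. The adjusted p of the myelin list was 0.681 with the genotype characteristic, where its direction reversed, 0.0710 with series matrix values, 0.0999 with array weights, 0.114 with the matrix assignment and 0.906 with an estimated correlation. Leaving out 1 array gave 0.00100 to 0.0725. With series matrix values the glucocorticoid, striatal and gliosis lists had an adjusted p of 0.0111 each, the immediate early genes 0.00802, and the synaptic vesicle list, reversed to higher, 0.0378. With the matrix assignment the glucocorticoid and gliosis lists had 0.0367 and the immediate early genes 0.0372. With the arrays whose labels are the same, where the knockout arm is knockout 1 alone against 2 wild-type arrays, the glucocorticoid, hippocampal and choroid plexus lists had 0.00395, the last reversed to higher, and gliosis 0.00748. The glucocorticoid list had 0.0183 with both labels, 0.906 with an estimated correlation, and 0.0463 to 0.5405 when 1 array was left out. With an estimated inter-gene correlation within each setting 0 lists passed by camera: the adjusted p of the lists given here was 0.472 to 0.477 with series matrix values, 0.536 with the matrix assignment, 0.852 with both labels, 0.484 to 0.563 with the arrays whose labels are the same, and 0.803 for the glucocorticoid list without wild type 5. Low signals limit NeoR-S in the wild type, Ccl21a and Ccl21c in the knockout and both unnamed probes in the wild type to bounds.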

Other observations

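The tests in this part were chosen after the values were seen, and so were the genes. Of 7 measured glucocorticoid-responsive transcripts, 4 were highest on wild type 1, 2 and 3, and the other 3 were not. Sgk1, a kinase induced by glucocorticoids, was between 11.88 and 12.13 on wild type 1, 2 and 3, and between 10.14 and 10.68 on wild type 4, wild type 5 and all knockout arrays. Cdkn1a, the cell cycle inhibitor p21, was between 8.46 and 8.93 on the same 3 arrays and between 7.43 and 7.87 on the others. Arrdc2 was between 7.84 and 8.32 there and at most 7.50 elsewhere, and Errfi1 between 9.08 and 9.56 there and at most 8.99 elsewhere. Egr2, an activity-regulated transcription factor from another list, was 7.40, 7.60 and 8.19 on wild type 1, 2 and 3 and at most 7.03 elsewhere. The other measured genes of that list, the immediate early genes, did not follow this pattern. Junb was 8.15 on knockout 4 against 7.99 on wild type 2.

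Region markers differed widely between animals of one group. Drd1, the dopamine receptor of striatal projection neurons, was 7.87 on knockout 1 and 7.25 on knockout 2, and at least 9.23 on the other 7 arrays. Ido1, another striatal transcript, was 6.96 and 6.87 on knockout 1 and knockout 2 and at least 7.67 elsewhere. Tcf7l2, a transcription factor of thalamic neurons, was 9.94 on knockout 2, 9.07 on wild type 2, 9.11 on wild type 3, 8.10 on wild type 1 and 8.45 on knockout 1, and between 7.16 and 7.39 on wild type 4, wild type 5, knockout 3 and knockout 4. C1ql2, a dentate gyrus transcript, was 9.72 on knockout 1, 8.84 on wild type 3, 8.63 on knockout 2 and 7.93 on wild type 2, and between 6.93 and 7.19 on the other 5 arrays.

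Abcb9 and Camkk2, the named genes of smallest p by title, lie on 1 chromosome in the gene table with 44 genes between them. Of 9 measured genes between them 1 had an unadjusted p under 0.05.

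The unnamed probes with the smallest p had identifiers with numbers close to each other. Among the 20 numbered probes with smallest p, ranks 1 to 4 had numbers from 24337 to 25514. Both unnamed probes called by title are among these 4. A hypothesis was that such numbers gather more than chance gives. In random draws of 20 from 7047 numbered probes, a share of 0.395 held a window of 1500 numbers at least as full. Chance placement of 4 among 20 was thus not excluded. The draws ignored rank, so they cannot decide whether ranks 1 to 4 gathered by chance.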
